A study of Macaca mulatta with 45 samples.

How the data were processed

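Gene expression was measured on human HT-12 V4 bead arrays with RNA of rhesus fat, per the labels, on 45 arrays of 24 animals. A monkey sequence that differs from a human probe lowers that probe's signal, so levels were compared between arrays for one gene and not between genes. The authors deposited a table with an intensity for each of 47323 probes on each array, exported with GenomeStudio 1.9.0 per the labels, as average bead signals on a linear scale that were not scaled between arrays. Beside each intensity the table holds a detection p-value, per the file headers, and how it was made is not given in the sources used here. A second deposited table holds a score for each probe and array. That deposited score equals, to within 5e-10, the log of the intensity minus the array's mean and divided by its standard deviation, and the step that made it is not given in the sources used here.

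In the subcutaneous arrays 92 probes were empty, and the other 47231 were used. The list of probes gave a single symbol for 30113 of these, several for 8 and none for 17110. Probes without a single symbol were kept out of the counts of genes and are given apart.

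Intensities were background corrected and quantile normalized together over all 45 arrays with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values and adds an offset of 16 before taking log2. Probes were kept when, in at least 1 group of a fit, they had a detection p under 0.05 on no fewer arrays than they were undetected on. For genes with several kept probes, the probe with the highest mean over the fit's arrays was used. Visceral comparisons came from a fit of the 10 visceral arrays (20190 probes kept, 11657 genes, 7 residual degrees of freedom). Subcutaneous comparisons came from a fit of 35 arrays (21710 probes, 12130 genes, 29 degrees of freedom), and comparisons of depots from a fit of all 45 (23767 probes, 12917 genes, 36 degrees of freedom). Each fit had 1 mean per group and was tested with lmFit and eBayes of limma with a variance trend. The p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, 16 comparisons were made, and an adjusted p under 0.05 counted as passing. Every p is of limma's moderated test, two-sided. Changes are differences of log2 intensity, with standard errors of the fit, and group values are means with standard deviations. The spread is pooled over all groups of a fit, to which a group of 2 arrays adds 1 degree of freedom.

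The groups, the comparisons, the tests, 29 gene lists, the 15 fixed genes, the rule for naming genes and most alternatives were set before the data were examined. By that rule the text could name the 5 genes with the largest rise and the 5 with the largest fall among those passing. Where fewer than 3 passed in a direction, it could name the 3 with the smallest unadjusted p in that direction. It could also name up to 4 members of a list with the smallest unadjusted p, and the 15 fixed genes. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry. The ranges over the alternatives include fry, which tests a list against no change and not against other genes. For each list the number of members passing is given over all genes tested and adjusted over the list alone. A list is described by the median change of its measured members. The correlation between the effects of diet and resveratrol was computed across genes, and again in 100 simulations with no effect and with the HFS arrays split between the effects.

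The labels state no pairing. The replicate numbers and the animal names of the deposited columns were compared, where 25 names stand for 24 animals. Of these 2 are alike but for the last character, probably 1 animal, and were kept as spelled, which touches only the random block of the depot fits. All 11 of the 24-month subcutaneous arrays share an animal with a baseline array, and 9 of the 11 pairs of the same number over time within a diet came from 1 animal (2 of 2 standard-diet, 4 of 5 HFS and 3 of 4 resveratrol). The replicate block thus joins different animals for 1 HFS and 1 resveratrol pair, and the animal blocks do not. Across the 11 pairs, residuals correlated at r = -0.331 to 0.476, with 8 above 0.1. Of 20 pairs of the same number across diets or depots 2 shared an animal. Unpaired fits, kept as planned, ignore pairs over time, so values with replicate and animal blocks stand beside those results. List tests were not repeated with the block. The array sets were read from the number of decimals in the deposited table and from the brightness of the arrays, since the labels name no batch.

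The alternatives were an adjusted p under 0.1, quantile normalization of log2(signal + 16) without background correction, the deposited z scores, background correction with median scaling, and depots normalized separately. Further ones were no filter, a stricter filter (detection p under 0.01 on every array of a group), no variance trend, every probe, only the arrays of the groups compared, all 45 arrays in 1 fit, array weights, the array set as a block, the replicate block, and leaving out each replicate of groups of up to 5 arrays. Added after the data were seen were fits within an array set, an animal block with the array set as a term or within set A, an animal as a random block, splits that move all arrays of an animal together, the number of probes detected as a covariate, and leaving out arrays in the correlation of effects. The array set stood in for the planned chip block. Splits of the arrays were counted in all possible ways up to 100 and otherwise drawn 100 times with a seed of 1.

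The fits were tested on simulated data with known changes in the design of each comparison. Changes of log2 1 were recovered at 46.3% in visceral fat between resveratrol and HFS and at 22.4% between HFS and the standard diet. In subcutaneous fat at 24 months, 55.2% were recovered between resveratrol and HFS, and over time 68.7% on HFS and 65.7% with resveratrol. The tools also included statmod 1.5.0, version 1.17.8 of data.table, and Python 3.11.15 with matplotlib 3.10.9 for the figures.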

Results

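Gene expression was measured on 45 bead arrays in fat of adult male rhesus monkeys. Per the labels, 24 animals were assigned to 3 diets. The standard diet (4 animals) drew 13% of its energy from fat. The high-fat, high-sucrose diet (HFS, 10 animals) drew 42%. A further 10 animals ate HFS with resveratrol, a plant polyphenol, at 80 mg per day in the first year and 480 mg in the second. Subcutaneous fat was collected before the diets (4 standard-diet, 10 HFS and 10 resveratrol arrays) and after 24 months (2, 5 and 4 arrays). Visceral fat was collected after 24 months (2, 4 and 4 arrays). Between 14386 and 18673 probes were detected per array, and log2 signals correlated between arrays of one group at Pearson r = 0.9092 to 0.9873 across 15181 probes. In subcutaneous fat at 24 months, 17770 ± 759 probes (mean ± standard deviation, n = 4) were detected in the resveratrol group and 16010 ± 272 (n = 5) in the HFS group. In visceral fat the numbers were 16160 ± 796 (n = 4) and 15170 ± 166 (n = 4). The subcutaneous arrays fell into 2 sets of unlike brightness, called array sets A and B here. Median signals were 48.47 to 59 in the 19 arrays of set A and 77.8 to 97.3 in the 16 arrays of set B. All 24-month subcutaneous arrays lay in set A, with 2 standard-diet, 3 HFS and 3 resveratrol baseline arrays, and the 10 visceral arrays were taken as a set of their own.

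**Figure D1:**
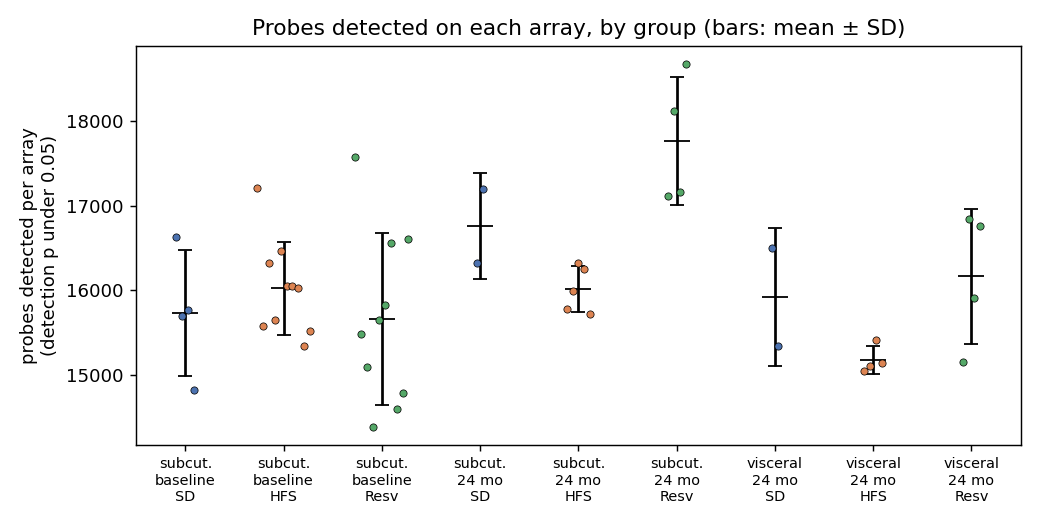
Probes with a detection p under 0.05 on each array, by depot, time and diet, with 1 point per array and bars for the mean and standard deviation. The 4 resveratrol arrays of subcutaneous fat at 24 months lay between 17117 and 18673, above all 5 HFS arrays of that time.

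The first comparison asked what the HFS diet did to visceral fat. Of 11657 genes tested, 1 differed between the HFS and the standard-diet group. IMP3, which encodes a part of the nucleolar complex that processes ribosomal RNA, was higher by 3.53 ± 0.30 (log2, ± standard error, adjusted p = 0.00175), in 4 of 4 HFS arrays. Its normalized log2 intensity was 8.02 ± 0.17 on HFS (standard deviation, n = 4) and 4.49 ± 0.04 on the standard diet (n = 2), where both arrays lay below detection, so the difference is a lower bound. The 2 standard-diet animals were already at 4.41 and 4.83 in their baseline subcutaneous fat. At an unadjusted p under 0.05 limma gave 572 genes, against 583 that chance alone gives. The neuronal genes SNAP25, for vesicle release, and NEFL, for a neurofilament, were lower by log2 -2.66 and -1.05 on HFS without passing (adjusted p = 0.901 for both). The count of 1 became 2 without standard-diet replicate 1, 8 without standard-diet replicate 2 and 2 without HFS replicate 3.

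**Figure D2:**
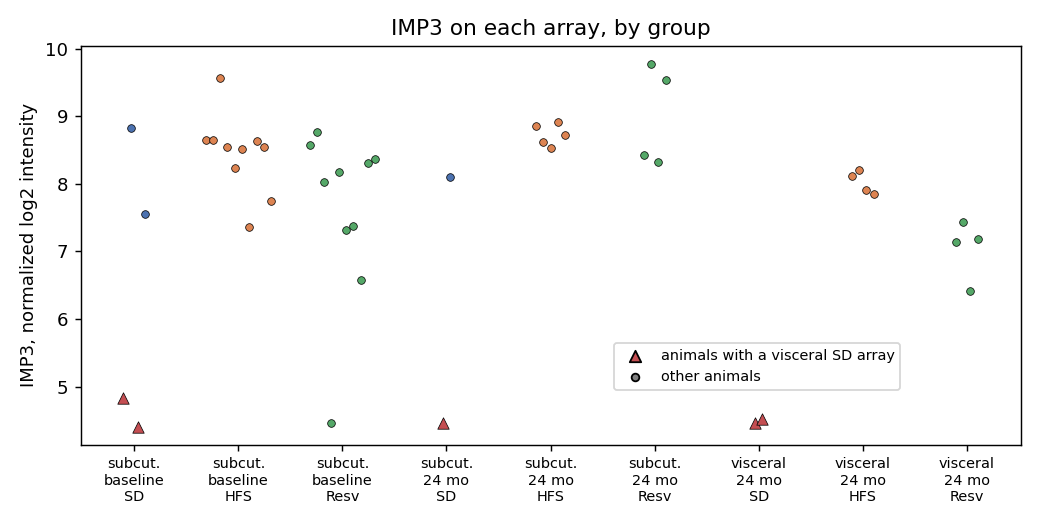
Normalized log2 intensity of IMP3 on each array by depot, time and diet (SD on the axis is the standard diet), with 1 point per array and triangles for the animals that have a visceral array of the standard diet. They lay between 4.41 and 4.83 at baseline and between 4.46 and 4.52 in visceral fat.

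Markers of the mesothelium, the cell layer that covers visceral fat, formed the group with the largest shift in that comparison. The median over 11 markers was -1.52, 10 of them lay below 0, and 0 passed alone (camera adjusted p = 4e-05, or adjusted p = 0.756 with an estimated correlation, and 8.99e-06 to 0.782 over the alternatives). MSLN, a mesothelial surface protein, was at -2.12 ± 0.66, the keratin KRT19 at -2.80 ± 1.16 and the junction gene CLDN15 at -1.91 ± 0.85. PKHD1L1 was at -1.20 ± 0.49. The values hang on the 2 standard-diet arrays. Without replicate 1 the median was -0.97 and the list was no longer called (camera adjusted p = 0.303), with MSLN at -1.05 and KRT19 at -1.40. Without replicate 2 the median was -2.20, with MSLN at -3.19 and KRT19 at -4.20. Genes of antigen presentation by MHC class II were higher at a median of 0.53 (10 of 10 above 0, 0 passing, camera adjusted p = 0.0163, or adjusted p = 0.756 with an estimated correlation, and 0.000325 to 0.883 over the alternatives). Among them HLA-DMA, which loads peptides, was at 0.52 ± 0.17. Erythroid markers, a sign of blood in the tissue, were higher at a median of 0.62 (6 of 7 above 0, 0 passing, camera adjusted p = 0.018, or adjusted p = 0.756 with an estimated correlation, and 0.00468 to 0.782 over the alternatives), with ALAS2 at 1.47 ± 0.45 and HBA1 at 1.04 ± 0.38. In all, 9 of 29 lists were called with the preset correlation and 0 with the estimated one. Of 15 genes fixed beforehand for insulin action, adipokines and inflammation, 12 were tested and 0 passed at an adjusted p from 0.901 up, and 0 had an unadjusted p under 0.05. Their changes ran from -0.29 for LEP, the adipocyte hormone leptin, to 0.95 for CCL2, a monocyte attractant. The mitochondrial carrier UCP2 was at 0.79 ± 0.58. IRS1, the adaptor of the insulin receptor, was at -0.19 ± 0.32.

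The second comparison, the effect of resveratrol on visceral fat under the same diet, bears on the study's question of insulin signalling and inflammation in fat. No single gene passed in limma (0 of 11657, smallest adjusted p = 0.102), although 2765 genes had an unadjusted p under 0.05. Of the 35 splits of these arrays 2 gave as many, the real one included, and another 2985. Without resveratrol replicate 1 the count was 1515, with 974 higher and 541 lower. It was 311 with only the arrays of the groups compared, 869 with all 45 arrays in 1 fit and 3354 with array weights, and 0 in limma with probes detected as a covariate, with 751 at an unadjusted p under 0.05. Matrix genes were among the larger differences, and none of them passed. BGN, the proteoglycan biglycan, was at 2.38 ± 0.44, or 12.48 ± 0.50 in the resveratrol group against 10.10 ± 0.69 on HFS (standard deviations, n = 4 each, adjusted p = 0.102). ELN, the elastin gene, was at 1.58 ± 0.24. COL6A2, a collagen VI chain, was at 4.04 ± 0.87, with resveratrol replicate 1 at 6.99 and the other resveratrol arrays between 9.89 and 10.22. CCN2, a growth factor of scarring tissue, was at 1.36 ± 0.31. These genes were above the HFS mean in 4 of 4 resveratrol arrays, at an adjusted p of 0.102 for each.

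As a list, the matrix genes were higher at a median of 0.32 (20 of 29 above 0, 0 passing, camera adjusted p = 0.00197, or adjusted p = 0.947 with an estimated correlation, and 9.22e-05 to 0.947 over the alternatives). Adjusted over the list alone, 9 were higher and 1 lower. Smooth muscle and pericyte markers were higher at a median of 0.81 (8 of 11 above 0, 0 passing, camera adjusted p = 0.00423, or adjusted p = 0.947 with an estimated correlation, and 3.15e-05 to 0.947 over the alternatives). Adjusted over the list alone, 5 were higher and 0 lower. The muscle filament gene DES was at 2.15 ± 0.38 and the pericyte proteoglycan CSPG4 at 0.81 ± 0.19. FOXS1, a transcription factor of vessel wall cells, was at 0.85 ± 0.14. CCN2, DES, CSPG4 and FOXS1 were undetected on all 4 HFS arrays, so their differences are lower bounds. Interferon response genes were lower at a median of -0.57 (14 of 16 below 0, 0 passing, camera adjusted p = 0.0415, or adjusted p = 0.947 with an estimated correlation, and 0.00611 to 0.947 over the alternatives). Adjusted over the list alone, 5 were lower and 0 higher. Of these antiviral genes ISG15 was at -1.83 ± 0.55, IFI44L at -1.07 ± 0.33 and MX1 at -0.89 ± 0.31, each below the HFS mean in 4 of 4 resveratrol arrays. Cell cycle genes were higher at a median of 0.52 (16 of 18 above 0, 0 passing, camera adjusted p = 0.00226, or adjusted p = 0.947 with an estimated correlation, and 5.74e-05 to 0.947 over the alternatives). Endothelial markers did not pass as a list (median 0.44, 0 of 14 passing, camera adjusted p = 0.055), and 6 were higher and 2 lower adjusted over the list alone. CLDN5, which seals junctions between endothelial cells, was at 1.49 ± 0.30.

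No gene of lipid handling passed in that comparison. LIPE and MGLL, which release fatty acids from stored fat, were at 1.88 ± 0.41 and 1.26 ± 0.33, and the lipolysis list had 4 higher and 0 lower of 13 adjusted over the list alone. The list's median was -0.08 and its mean 0.16, and it was not called (0 passing, camera adjusted p = 0.554). The synthesis genes FASN and SREBF1 were at 1.55 ± 0.45 and 1.68 ± 0.48, while the median of their list was -0.07 and its mean 0.02 (0 of 17 passing, camera adjusted p = 0.917). CEBPA, a regulator of the adipocyte state, was at 0.89 ± 0.17. TSPO, a mitochondrial outer membrane protein, was at 1.09 ± 0.18. Lower in the resveratrol group without passing were the dynein chain DYNLT2 (-1.74 ± 0.28), the small heat shock gene HSPB8 (-0.97 ± 0.16) and the cilium gene IFT57 (-1.21 ± 0.22). Insulin signalling genes had a median of 0.02 (11 of 20 above 0, 0 passing, camera adjusted p = 0.958). Inflammatory cytokines had a median of -0.03 and a mean of 0.23 (0 of 19 passing, camera adjusted p = 0.832). Of the 15 fixed genes, 12 were tested and 0 passed, and 1 had an unadjusted p under 0.05, the glucose transporter gene SLC2A4 at 0.46 ± 0.18 (adjusted p = 0.158), close to the array's floor. LEP was at -0.35 ± 0.20 and CCL2 at 0.16 ± 0.70.

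**Figure D3:**
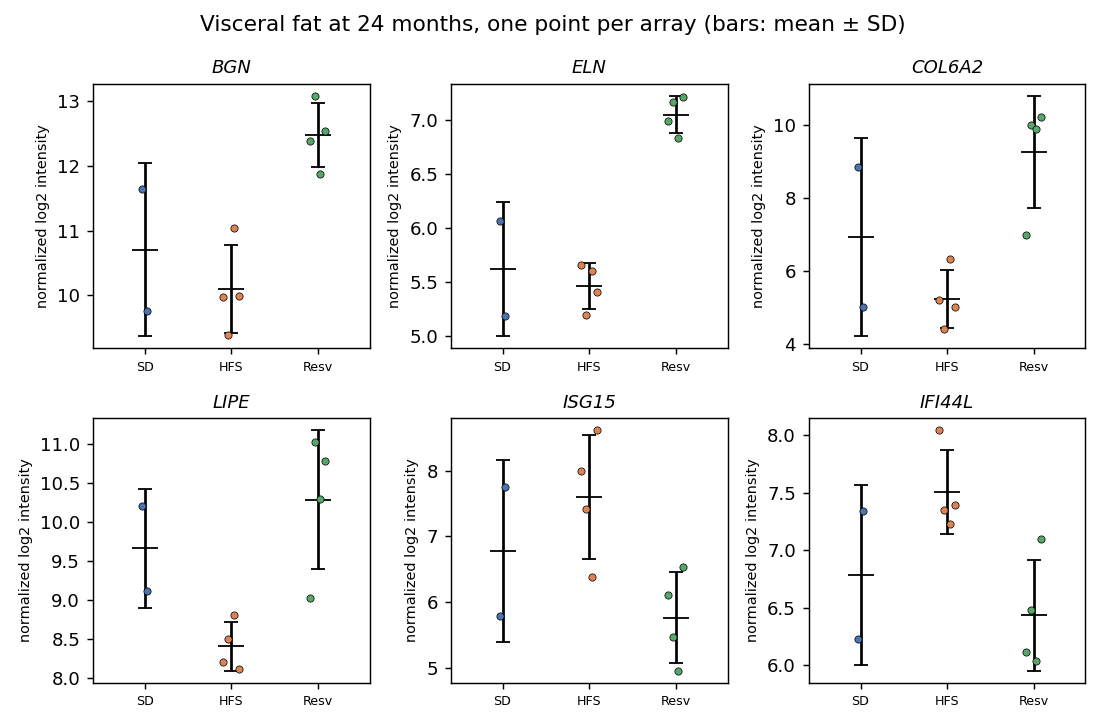
Normalized log2 intensity of 6 genes in visceral fat at 24 months, by diet, with 1 point per array and bars for the mean and standard deviation. BGN averaged 12.48 in the resveratrol group and 10.10 on HFS, and ISG15 averaged 5.77 and 7.60, with no gene past the threshold.

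Visceral fat of the resveratrol group was also set against the standard diet. Of 11657 genes, 1 differed, with 1153 at an unadjusted p under 0.05. IMP3 was higher by 2.55 ± 0.30 (adjusted p = 0.0452) in 4 of 4 resveratrol arrays, again a lower bound, with the animals' baseline difference given above. The count of 1 became 2 without standard-diet replicate 2, 3 without resveratrol replicate 1, and 0 without resveratrol replicate 2 or 4. SNAP25, undetected on all 4 resveratrol arrays, was lower at -3.33 ± 0.53 without passing (adjusted p = 0.302). The pyrophosphatase gene NUDT14 was at 1.65 ± 0.33 and EXOC3L1, a part of the secretion machinery, at 0.98 ± 0.20, and neither passed. LEP was at -0.64 ± 0.25 (adjusted p = 0.471). Cell cycle genes shifted by a median of 0.87 (17 of 18 above 0, 0 passing, camera adjusted p = 7.58e-08, or adjusted p = 0.487 with an estimated correlation, and 3.44e-10 to 0.487 over the alternatives). Mesothelial markers shifted by -1.18 (10 of 11 below 0, 0 passing, camera adjusted p = 0.0168, or adjusted p = 0.506 with an estimated correlation, and 8.42e-06 to 0.984 over the alternatives). That median was -0.20 without standard-diet replicate 1, -2.26 without replicate 2 and -0.68 without resveratrol replicate 1. In all 9 of 29 lists were called with the preset correlation and 0 with the estimated one. Smooth muscle and pericyte (median 0.74), endothelial (0.67) and macrophage markers (0.42) were among them.

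In subcutaneous fat at 24 months, HFS against the standard diet gave 0 genes of 12130 in limma (smallest adjusted p = 0.129), and 229 at an unadjusted p under 0.05 against 606 from chance. Without standard-diet replicate 1 the count was 22, without standard-diet replicate 2 it was 5, and without HFS replicate 1 it was 1. The nearest to the threshold were the dynein-like gene DNHD1 (-0.47 ± 0.09, adjusted p = 0.129), the stress-induced nuclear receptor NR4A3 (-1.56 ± 0.34, adjusted p = 0.345) and the lipoprotein receptor LRP8 (-0.55 ± 0.12, adjusted p = 0.378) on the lower side, with DNHD1 and LRP8 undetected on all 5 HFS arrays. On the higher side stood POLR2J3, a subunit gene of RNA polymerase II, at 2.30 ± 0.57 (adjusted p = 0.634) and AAMDC, a gene of fat cell formation, at 3.87 ± 1.09 (adjusted p = 1). POLR2J3 was at 0.73 without standard-diet replicate 1 and at 3.88 without replicate 2 (adjusted p = 0.00264). Immediate early and heat shock genes, which also respond to handling of tissue, were lower at a median of -0.37 (18 of 19 below 0, 0 passing, camera adjusted p = 0.000315, or adjusted p = 0.838 with an estimated correlation, and 1.58e-06 to 0.991 over the alternatives). Erythroid markers were higher at a median of 0.76 (7 of 8 above 0, 0 passing, camera adjusted p = 0.00101, or adjusted p = 0.838 with an estimated correlation, and 1.94e-09 to 0.991 over the alternatives), with ALAS2 at 1.39 ± 0.92 and HBA1 at 1 ± 0.61. Of the 15 fixed genes, 11 were tested and 0 passed, all at an adjusted p of 1, and 0 had an unadjusted p under 0.05. IRS1 was at 0.05 ± 0.40, LEP at 0.09 ± 0.27 and CCL2 at 0.52 ± 0.91. Their signs turned without 1 of the standard-diet arrays. The erythroid median was 0.12 without replicate 1, and the immediate early median was 0 without replicate 2.

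Resveratrol against HFS in subcutaneous fat at 24 months changed 271 of 12130 genes, with 238 higher and 33 lower. Matrix genes, stress response genes and a kinase of insulin signalling were among them. The largest rises were those of PCOLCE2, an enhancer of collagen processing (2.12 ± 0.51, adjusted p = 0.0163), COL3A1, the collagen III chain (2.11 ± 0.53, adjusted p = 0.0254), and DUSP1, a phosphatase that ends MAP kinase signals (2.11 ± 0.27, adjusted p = 6.49e-06). HMGB1, a chromatin protein that also acts as a danger signal, rose by 1.73 ± 0.41 (adjusted p = 0.0131), and PTGES3, a co-chaperone, by 1.66 ± 0.40 (adjusted p = 0.0163). All 5 were above the HFS mean in 4 of 4 resveratrol arrays. DUSP1 averaged 7.07 ± 0.91 against 4.97 ± 0.24, and COL3A1 9.23 ± 1 against 7.12 ± 0.88 (standard deviations, n = 4 and 5). The largest falls were those of the inositol carrier SLC5A3 (fell by 1.45 ± 0.39, adjusted p = 0.0388), the pseudogene CEP170P1 (fell by 1.44 ± 0.37, adjusted p = 0.0272), USE1, of transport to the endoplasmic reticulum (fell by 1.12 ± 0.28, adjusted p = 0.0212), and USF1, a transcription factor of lipid genes (fell by 1.11 ± 0.28, adjusted p = 0.0247). The ubiquitin ligase gene DTX3L fell by 1.04 ± 0.28 (adjusted p = 0.0328).

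Among the insulin signalling genes of that comparison, GSK3B, the kinase that holds back glycogen synthesis until insulin acts, fell by 0.94 ± 0.20 (adjusted p = 0.00623), in 4 of 4 resveratrol arrays. The list as a whole did not shift (median -0.07, 1 lower, 0 higher and 18 not passing of 19, camera adjusted p = 0.844). Of the 15 fixed genes, 11 were tested, 0 passed and 2 had an unadjusted p under 0.05. SIRT1, the deacetylase often named as resveratrol's target, was at 1.31 ± 0.46 (adjusted p = 0.148), LEP at 0.49 ± 0.22 (adjusted p = 0.315), IRS1 at -0.14 ± 0.32 and CCL2 at 0.61 ± 0.73. IL6, an inflammatory cytokine, was at -0.14 ± 0.47, and at 0.11 with the deposited z scores, where IRS1 was at 0.19. Inflammatory cytokines had a median of 0.18 (0 of 21 passing, camera adjusted p = 0.209), and 2 were higher adjusted over the list alone. These were PTGS2, the inducible prostaglandin synthase (1.19 ± 0.37), and the receptor TLR2 (0.38 ± 0.12), which was at -0.15 with median scaling. Matrix genes had a median of 0.12, with 2 higher, 0 lower and 28 not passing (camera adjusted p = 0.209), and 3 higher and 1 lower adjusted over the list alone. The second of the matrix genes that rose was TIMP2, an inhibitor of matrix proteases (1.04 ± 0.24, adjusted p = 0.0124). Immediate early and heat shock genes rose as a list by a median of 0.36 (1 higher, 0 lower and 18 not passing, camera adjusted p = 0.0143, or adjusted p = 0.932 with an estimated correlation, and 0.000541 to 0.932 over the alternatives), and 1 was higher adjusted over the list alone.

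Genes of protein folding stress moved apart in that comparison. EIF2AK3, a sensor kinase of the endoplasmic reticulum, rose by 0.82 ± 0.18 (adjusted p = 0.00735) and the folding enzyme PDIA4 by 0.47 ± 0.07 (adjusted p = 7.76e-05), near the floor and at -0.07 with median scaling. DDIT3, a factor of stress-induced cell death, fell by 0.77 ± 0.21 (adjusted p = 0.0469). Their list had a median of -0.24 and a mean of -0.06 while the test pointed up (2 higher, 1 lower and 9 not passing, camera adjusted p = 0.769), and the same 2 and 1 counts held adjusted over the list alone. CAT, the antioxidant enzyme catalase, rose by 1.63 ± 0.40 (adjusted p = 0.0216), USP18, a brake on interferon signals, by 0.65 ± 0.18 (adjusted p = 0.0401), and NDUFB5, of respiratory complex I, by 0.82 ± 0.22 (adjusted p = 0.034). The ribosomal protein gene RPS3 fell by 0.96 ± 0.26 (adjusted p = 0.0442). The count of 271 was 98 without resveratrol replicate 4 and 368 within array set A, and it was 6 with median scaling, which moved the median of all genes to -0.26. It was 35 with the number of probes detected as a covariate. PDIA4 and TLR2 were undetected on all 5 HFS arrays.

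**Figure D4:**
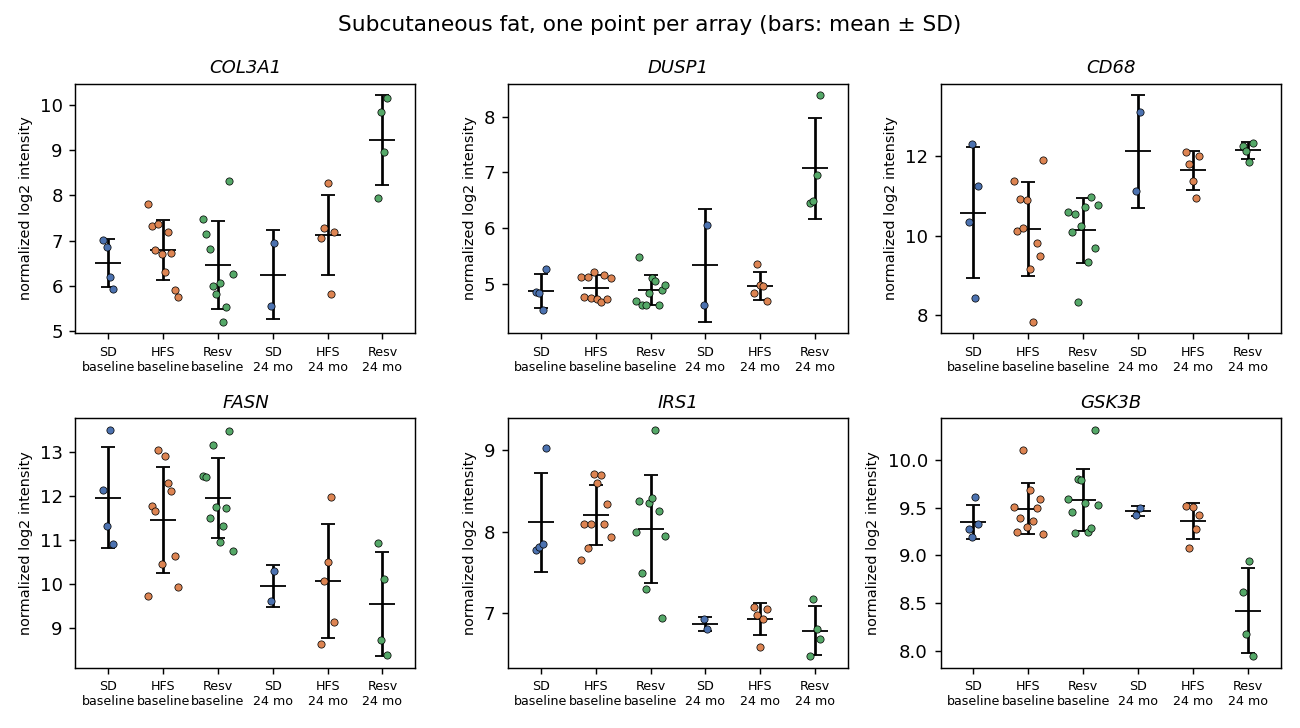
Normalized log2 intensity of 6 genes in subcutaneous fat by diet and time, with 1 point per array and bars for the mean and standard deviation. DUSP1 averaged 7.07 in the resveratrol group at 24 months against 4.97 on HFS, and GSK3B averaged 8.42 against 9.36, while IRS1 was lower at 24 months than at baseline in all 3 diets and averaged 6.87 in the standard-diet group at 24 months (2 arrays), where the difference did not pass.

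Resveratrol against the standard diet in subcutaneous fat at 24 months changed 96 of 12130 genes, with 90 higher and 6 lower. COL3A1 rose by 2.99 ± 0.69 (adjusted p = 0.023), HMGB1 by 2.16 ± 0.52 (adjusted p = 0.0354), the TGF-beta co-receptor TGFBR3 by 1.87 ± 0.44 (adjusted p = 0.0286) and DUSP1 by 1.74 ± 0.35 (adjusted p = 0.00606). NR4A3 fell by 1.43 ± 0.35 (adjusted p = 0.0373), RSPRY1 by 1.05 ± 0.25 (adjusted p = 0.0286) and GSK3B by 1.04 ± 0.26 (adjusted p = 0.0425). Each of these held in 4 of 4 resveratrol arrays. Of 29 lists 0 were called, and of the 15 fixed genes 11 were tested, 0 passed and 0 had an unadjusted p under 0.05. The count was 23 without standard-diet replicate 2 and 123 within array set A. With median scaling it was 0 in limma, with 1632 genes at an unadjusted p under 0.05 and the median of all genes at -0.29.

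The baseline arrays, taken before the diets, gave the background for these contrasts. HFS against the standard diet gave 1 gene of 12130, with 356 at an unadjusted p under 0.05. The zinc finger gene ZNF665 fell by 0.40 ± 0.07 (adjusted p = 0.0102, 10 of 10 HFS arrays), but its probe was undetected on all baseline arrays of both groups, so the call rests on values at background. The count was 0 without standard-diet replicate 2 or 4 and 3 without standard-diet replicate 3. The oxidase gene CYP4F12 (1.36 ± 0.35) and the gut peptide gene NTS (1.47 ± 0.38) did not pass (adjusted p = 0.939 for both). Adipocyte identity genes were lower at a median of -0.23 (17 of 19 below 0, 0 passing, camera adjusted p = 0.0072, or adjusted p = 0.273 with an estimated correlation, and 0.000244 to 0.755 over the alternatives). Within array set A the count was 1, a gene other than ZNF665. Median scaling moved the median of all genes to -0.16. Resveratrol against HFS at baseline gave 0 genes in limma, with 288 at an unadjusted p under 0.05, and 0 within array set A with 416. The RNA export gene PHAX (0.56 ± 0.13), the mitotic kinase AURKB (-0.71 ± 0.17) and FMC1, of mitochondrial ATP synthase assembly (0.36 ± 0.09), all had an adjusted p of 1. Erythroid markers were lower at a median of -0.84 (6 of 8 below 0, 0 passing, camera adjusted p = 6.96e-06, or adjusted p = 0.157 with an estimated correlation, and 6.03e-06 to 0.413 over the alternatives), and 5 were lower adjusted over the list alone. Macrophage and monocyte markers were also lower before the diets, at a median of -0.24 (20 of 23 below 0, 0 passing, camera adjusted p = 0.0316, or adjusted p = 0.95 with an estimated correlation, and 0.0312 to 0.998 over the alternatives), as were cell cycle genes (-0.15). In all 3 lists were called and 0 with the estimated correlation.

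**Figure D5:**
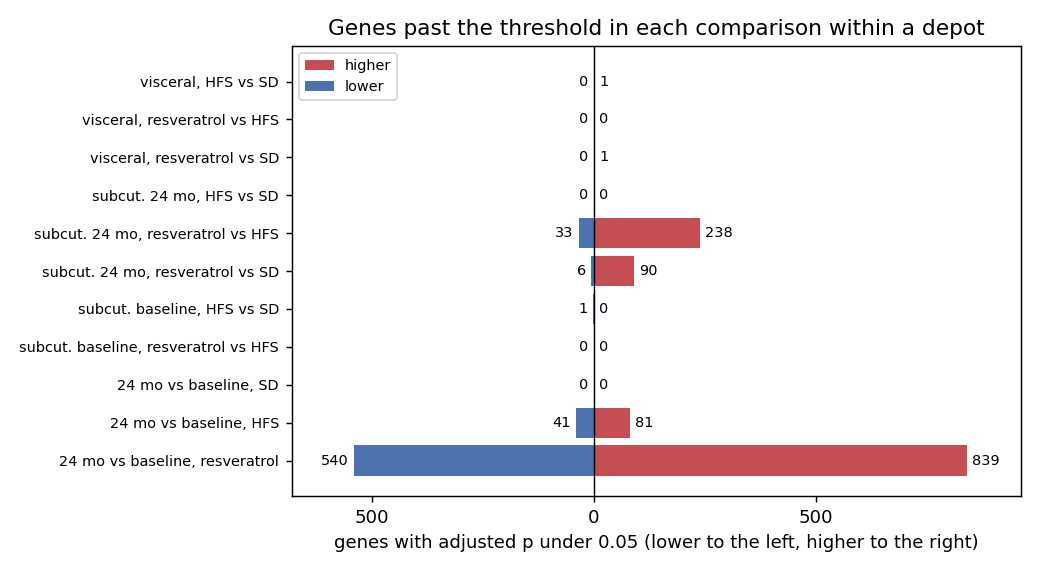
Genes with an adjusted p under 0.05 in each comparison within a depot, as bars to the right for higher and to the left for lower. Resveratrol against HFS at 24 months had 238 higher and 33 lower in subcutaneous fat and 0 in visceral fat.

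Change over time was measured in subcutaneous fat within each diet. In the standard-diet group 0 of 12130 genes passed in limma, with 954 at an unadjusted p under 0.05. FOLH1, a folate hydrolase, and the small nucleolar RNA SNORD139 lay on the threshold (0.50 ± 0.09 and 1.06 ± 0.20, adjusted p = 0.05 for both), and the microRNA gene MIR367 was at 0.38 ± 0.08 (adjusted p = 0.0808). All 3 were undetected on the 4 baseline arrays, and FOLH1 and MIR367 on 1 of the 2 later ones, so these values lie near background. The count was 1 without baseline replicate 2 or 4, 47 without 24-month replicate 1 and 11 without 24-month replicate 2. It was 149 with the array set as a block and 5 within array set A. With the replicate block it was 0 in limma, with 1484 at an unadjusted p under 0.05. It was 20 with an animal block and the set as a term, 76 with an animal block within set A and 9 with an animal as a random block. Of the 15 fixed genes, 11 were tested and 0 passed, and 3 had an unadjusted p under 0.05. IRS1 was at -1.25 ± 0.41 (adjusted p = 0.422), from 8.12 ± 0.61 (n = 4) to 6.87 ± 0.09 (n = 2), PPARGC1A at -1.78 ± 0.61 (adjusted p = 0.438), IL6 at 1.32 ± 0.61 (adjusted p = 0.601) and CD68 at 1.54 ± 0.82 (adjusted p = 0.676), each in 2 of 2 arrays. With median scaling the median of all genes was at 0.14. Genes of fatty acid and triglyceride synthesis were lower at a median of -0.91 (19 of 19 below 0, 0 passing, camera adjusted p = 0.00011, or adjusted p = 0.24 with an estimated correlation, and 6.86e-07 to 0.24 over the alternatives). Macrophage and monocyte markers were higher at a median of 0.95 (20 of 23 above 0, 0 passing, camera adjusted p = 0.00142, or adjusted p = 0.404 with an estimated correlation, and 5.84e-06 to 0.818 over the alternatives). That median was 0.12 without 24-month replicate 2 (camera adjusted p = 0.818). Immediate early and heat shock genes were higher at a median of 0.61 (18 of 19 above 0, 0 passing, camera adjusted p = 4.44e-05, or adjusted p = 0.198 with an estimated correlation, and 4.75e-08 to 0.352 over the alternatives), with 2 higher adjusted over the list alone. It was 0.09 without 24-month replicate 2. Erythroid markers were lower at a median of -1.37 (7 of 8 below 0, 0 passing, camera adjusted p = 5.36e-05, or adjusted p = 0.198 with an estimated correlation, and 1.68e-10 to 0.292 over the alternatives), with 2 lower adjusted over the list alone. It was -0.68 without 24-month replicate 1. Of 29 lists, 13 were called with the preset correlation and 0 with the estimated one.

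In the HFS group 122 of 12130 genes changed over time, with 81 higher and 41 lower. The largest rise was that of PLA2G2A, a secreted phospholipase of inflammation (3.80 ± 0.63, adjusted p = 0.00264), followed by MEST, a gene of fat cell growth (1.89 ± 0.49, adjusted p = 0.0494), and the interferon-induced GBP2 (1.89 ± 0.48, adjusted p = 0.0443). Each was above the baseline mean in 5 of 5 arrays. The secreted proteins MUCL1 (1.38 ± 0.33, adjusted p = 0.0347) and SFTPD (1.30 ± 0.31, adjusted p = 0.0364) rose in 4 of 5. IRS1, the adaptor of the insulin receptor, fell by 1.28 ± 0.26 (adjusted p = 0.0168), from 8.20 ± 0.37 (n = 10) to 6.92 ± 0.20 (n = 5), in 5 of 5 arrays, close to the difference of -1.25 that did not pass in the 2 standard-diet arrays. The sugar-sensing factor MLXIPL fell by 1.73 ± 0.41 (adjusted p = 0.0319), the pyruvate carboxylase gene PC by 1.71 ± 0.35 (adjusted p = 0.0174), the folate enzyme gene ALDH1L1 by 1.70 ± 0.43 (adjusted p = 0.0433) and ACACB, a gate of fatty acid oxidation, by 1.04 ± 0.26 (adjusted p = 0.042). NTS and the tetraspanin TSPAN8 fell by 1.42 ± 0.35 and 1.37 ± 0.31 (adjusted p = 0.0398 and 0.0294). The chaperone HSP90B1 rose by 0.65 ± 0.14 and the xenobiotic receptor AHR by 0.52 ± 0.11 (adjusted p = 0.0215 for both). With the replicate block, which joins arrays of the same number over time, 1 gene kept its call, PLA2G2A. With an animal block and the set as a term 283 passed, and 45 with an animal block within set A.

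Of the 15 fixed genes in the HFS group over time, 11 were tested and 1 passed, IRS1. IL6 (1.38 ± 0.39, adjusted p = 0.0713) and CD68, a macrophage protein (1.47 ± 0.52, adjusted p = 0.159), did not. The synthesis list fell by a median of -0.48 (0 higher, 2 lower and 17 not passing, camera adjusted p = 0.000856, or adjusted p = 0.358 with an estimated correlation, and 0.000305 to 0.358 over the alternatives), with 4 lower adjusted over the list alone. Macrophage and monocyte markers were higher at a median of 0.73 (0 of 23 passing, camera adjusted p = 9.11e-05, or adjusted p = 0.358 with an estimated correlation, and 4.2e-06 to 0.358 over the alternatives). Interferon response genes were higher at a median of 0.42 (0 of 15 passing, camera adjusted p = 0.000518, or adjusted p = 0.284 with an estimated correlation, and 0.000145 to 0.284 over the alternatives), with 4 higher adjusted over the list alone. Insulin signalling genes had a median of -0.12 (1 lower and 18 not passing, camera adjusted p = 0.095), with 3 lower adjusted over the list alone. Erythroid markers were lower at a median of -1.21 (0 of 8 passing, camera adjusted p = 0.000518, or adjusted p = 0.284 with an estimated correlation, and 4.89e-05 to 0.284 over the alternatives). The split of 81 higher and 41 lower was 38 and 43 with the deposited z scores and 541 and 77 with median scaling, which moved the median of all genes to 0.26. Within array set A the count was 22 (5 shared), and with the set as a block 543 (69 shared). It was 15 without HFS replicate 3 of the 24-month arrays.

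In the resveratrol group 1379 of 12130 genes changed over time, with 839 higher and 540 lower. The rises were led by MMP7, a matrix protease (3.63 ± 1.23, adjusted p = 0.0495), LIPA, the lysosomal acid lipase (3.30 ± 0.71, adjusted p = 0.00222), PRG4, the lubricant proteoglycan (2.90 ± 0.74, adjusted p = 0.00912), CCN3, a matrix signalling protein (2.85 ± 0.56, adjusted p = 0.000739), and COL3A1 (2.77 ± 0.47, adjusted p = 0.000132). The falls were led by the phosphodiesterase PDE8B (fell by 2.65 ± 0.48, adjusted p = 0.000266), FASN, the fatty acid synthase (fell by 2.40 ± 0.61, adjusted p = 0.00881), and the histone gene H4C3 (fell by 2.39 ± 0.63, adjusted p = 0.0113). GPM6B and SLC5A3 fell by 2.21 ± 0.54 and 2.16 ± 0.35 (adjusted p = 0.00629 and 5.13e-05). Insulin signalling lost IRS1 (fell by 1.25 ± 0.28, adjusted p = 0.00307), IRS2 (fell by 1.47 ± 0.42, adjusted p = 0.0195) and GSK3B (fell by 1.16 ± 0.18, adjusted p = 2.57e-05). That list had 3 lower and 16 not passing of 19, and 3 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.247).

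Of the 15 fixed genes 11 were tested in the resveratrol group over time and 7 passed, 5 higher and 2 lower. PPARGC1A, the driver of mitochondrial formation, fell by 1.86 ± 0.42 (adjusted p = 0.00296), beside IRS1. SIRT1 rose by 1.25 ± 0.40 (adjusted p = 0.0385), LEP by 0.60 ± 0.19 (adjusted p = 0.0378), IL6 by 1.28 ± 0.42 (adjusted p = 0.0418), CCL2 by 2.00 ± 0.64 (adjusted p = 0.038) and CD68 by 2.02 ± 0.56 (adjusted p = 0.0168). IRS1, PPARGC1A, IL6 and CD68 moved alike on the standard diet (0 passing). Of 11 changes 0 differed from HFS (lowest adjusted p 0.41), so none is shown particular to resveratrol. Macrophage and monocyte markers rose by a median of 1.15 (4 higher, 0 lower and 19 not passing, camera adjusted p = 0.000177, or adjusted p = 0.68 with an estimated correlation, and 8.26e-05 to 0.68 over the alternatives), with 10 higher adjusted over the list alone. The scavenger receptor CD163 and the receptor LYVE1 were among them (1.98 ± 0.47 and 1.77 ± 0.42). Inflammatory cytokines rose by a median of 0.37 (6 higher, 0 lower and 15 not passing, camera adjusted p = 0.00189, or adjusted p = 0.458 with an estimated correlation, and 0.000966 to 0.458 over the alternatives), with 7 higher adjusted over the list alone. PTGS2 was at 1.65 ± 0.33, TLR2 at 0.57 ± 0.10 and the inflammasome gene NLRP3 at 0.31 ± 0.06, the last 2 undetected on all baseline arrays.

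Matrix genes rose in the resveratrol group over time by a median of 0.51 (5 higher, 1 lower and 24 not passing, camera adjusted p = 0.003, or adjusted p = 0.68 with an estimated correlation, and 0.000512 to 0.68 over the alternatives), with 6 higher and 1 lower adjusted over the list alone. LUM, a collagen-binding proteoglycan, rose by 2.63 ± 0.51 (adjusted p = 0.000694). Immediate early and heat shock genes rose by a median of 0.48 (4 higher, 0 lower and 15 not passing, camera adjusted p = 0.00156, or adjusted p = 0.68 with an estimated correlation, and 0.000154 to 0.68 over the alternatives), with 5 higher adjusted over the list alone, DUSP1 (2.18 ± 0.24) and ATF3 (1.64 ± 0.47) among them. The unfolded protein response list rose by a median of 0.31 (3 higher, 0 lower and 9 not passing, camera adjusted p = 0.0102, or adjusted p = 0.458 with an estimated correlation, and 0.00199 to 0.458 over the alternatives), with 4 higher adjusted over the list alone and PDIA4 at 0.62 ± 0.06, undetected on all baseline arrays. The list was also called on the standard diet (0.25) and HFS (0.23). CAT rose by 2.04 ± 0.36. The fat cell regulators MLXIPL and CEBPA fell by 2.06 ± 0.44 and 1.06 ± 0.24 (adjusted p = 0.00193 and 0.00313). With probes detected as a covariate 128 passed, 120 among the 1379, whose signed median was 0.60 in place of 0.77. With the replicate block 790 passed, 515 among the 1379, and MMP7, H4C3, SIRT1, IL6, PTGS2 and NLRP3 no longer did. Within array set A 232 passed, 162 shared, and with the set as a block 637, 460 shared. An animal block gave 675 with the set as a term and 537 within set A. The split of 839 higher and 540 lower was 1369 and 442 with the deposited z scores and 457 and 477 with median scaling, which moved the median of all genes to -0.15. The count was 568 without 24-month replicate 4.

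Whether the change over time differed between the diets was tested as an interaction. Between the resveratrol and HFS groups 102 of 12130 genes differed, with 94 more positive and 8 more negative under resveratrol. The differences were 2.15 ± 0.33 for DUSP1 (adjusted p = 0.000205), 1.83 ± 0.41 for SH3BGRL, a small redox-like protein (adjusted p = 0.0205), 1.74 ± 0.44 for the tubulin gene TUBA3E (adjusted p = 0.0434), 1.53 ± 0.21 for PBDC1 (adjusted p = 3.51e-05) and 1.47 ± 0.29 for LAMP1, a lysosomal membrane protein (adjusted p = 0.00466). On the negative side stood USE1 (-1.31 ± 0.33, adjusted p = 0.0468), RSPRY1 (-1.09 ± 0.23, adjusted p = 0.0107), GSK3B (-1.03 ± 0.24, adjusted p = 0.0278) and the tRNA modifier ALKBH8 (-0.97 ± 0.23, adjusted p = 0.0287). PBDC1 was detected on 1 of 10 baseline arrays of either group and on 0 of 5 HFS arrays at 24 months, so its value is not exact. With the replicate block 0 genes passed in limma, with 1543 at an unadjusted p under 0.05. With probes detected as a covariate 6 passed, and 5 with an animal block and the set as a term. Within array set A it was 0 with 919, and with median scaling 0 with 2988 and the median of all genes at -0.31. With the deposited z scores 322 were more positive and 71 more negative, and the median of all genes was at 0.10. The count was 53 without 24-month resveratrol replicate 4. The immediate early list differed by a median of 0.41 (1 higher, 0 lower and 18 not passing, camera adjusted p = 0.012, or adjusted p = 0.918 with an estimated correlation, and 0.000521 to 0.918 over the alternatives), with 1 higher adjusted over the list alone. Between the HFS and standard-diet groups 0 genes differed in limma, with 1.81% of 12130 at an unadjusted p under 0.05. The count was 13 without standard-diet 24-month replicate 1, and median scaling moved the median of all genes to 0.13.

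The depots were compared at 24 months with equal weight for each diet. Between visceral and subcutaneous fat 5383 of 12917 genes differed, with 3072 higher and 2311 lower in visceral fat. The largest rises were in ITLN1, the omental lectin omentin (4.93 ± 0.31, adjusted p = 8.21e-16), the tight junction gene CGN (4.46 ± 0.28, adjusted p = 3.49e-16), the protease KLK11 (4.35 ± 0.30), the retinoic acid enzyme ALDH1A2 (3.98 ± 0.34) and KRT19 (3.89 ± 0.33). ITLN1, CGN, KLK11 and KRT19 were undetected on all 11 subcutaneous arrays, so these are lower bounds and their order is not exact. Lower in visceral fat were CCN3 (fell by 3.69 ± 0.40), ANGPTL5 (fell by 3.50 ± 0.36), TBX15, a patterning factor of subcutaneous fat (fell by 3.15 ± 0.16, adjusted p = 1.18e-18), the hydroxylase ASPH (fell by 3.07 ± 0.55) and STMN2, of nerve growth (fell by 3.00 ± 0.62). Mesothelial markers were higher at a median of 2.00 (8 higher, 1 lower and 2 not passing, camera adjusted p = 1.28e-06, or adjusted p = 0.0334 with an estimated correlation, and 9.76e-16 to 0.0334 over the alternatives), the same counts adjusted over the list alone. MSLN was at 3.10 ± 0.19, WT1 at 3.31 ± 0.23 and BNC1 at 3.33 ± 0.26, with MSLN and BNC1 also undetected in subcutaneous fat. Of the 65 list shifts called with the preset correlation in the 16 comparisons, 2 were also called with the estimated one, both of mesothelial markers, here and in the depot difference of the HFS effect, where the named markers had no measurable subcutaneous side.

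T, B and natural killer cell markers were higher in visceral fat at a median of 0.32 (8 higher, 0 lower and 10 not passing, camera adjusted p = 0.0181, or adjusted p = 0.483 with an estimated correlation, and 5.76e-07 to 0.483 over the alternatives), with 10 higher adjusted over the list alone. The killer cell protein GNLY was at 1.79 ± 0.22 and CD2 at 1.02 ± 0.18. Matrix genes were lower at a median of -0.27 (1 higher, 12 lower and 17 not passing, camera adjusted p = 0.0119, or adjusted p = 0.956 with an estimated correlation, and 0.000979 to 0.956 over the alternatives), the same counts adjusted over the list alone, with COL3A1 at -2.23 ± 0.34 and LUM at -2.35 ± 0.37. The position genes HOXB8 and HOXC8 went opposite ways, at 3.35 ± 0.25 and -2.42 ± 0.25. Of the 15 fixed genes, 13 were tested and 7 passed, with 4 higher and 3 lower. LEP fell by 1.54 ± 0.15 (adjusted p = 8.13e-11), SIRT1 by at least 1.36 ± 0.29 (adjusted p = 0.000233, detected on 1 of 10 visceral arrays) and CD68 by 1.35 ± 0.45 (adjusted p = 0.0142), while UCP2 rose by 1.92 ± 0.37 (adjusted p = 7.51e-05). The split of 3072 higher and 2311 lower was 2099 and 2718 with median scaling, which moved the median of all genes to -0.15. All visceral arrays were taken as 1 array set with no subcutaneous array, so depot and set cannot be told apart. The fit also treated arrays of the same animal in both depots as independent.

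The effect of resveratrol against HFS differed between the depots in 349 of 12917 genes, with 135 more positive and 214 more negative in visceral fat. The largest differences were those of COL6A2 (4.4 ± 1.26, adjusted p = 0.0474), CLDN5 (2.47 ± 0.67, adjusted p = 0.0341), DES (2.01 ± 0.49, adjusted p = 0.0204) and CEBPA (1.49 ± 0.37, adjusted p = 0.0222) on the positive side. On the negative side were PCOLCE2 (-2.57 ± 0.69, adjusted p = 0.0332), KANK1, which organises the cell edge (-2.54 ± 0.67, adjusted p = 0.0309), CAT (-2.31 ± 0.57, adjusted p = 0.0217), DUSP1 (-2.15 ± 0.36, adjusted p = 0.000632) and KDR, the VEGF receptor of endothelium (-0.95 ± 0.21, adjusted p = 0.0109). DUSP1 was undetected on all visceral arrays of both groups, so that difference comes from subcutaneous fat. PCOLCE2 and KDR were undetected on all visceral resveratrol arrays, DES on all visceral HFS and KDR on all subcutaneous HFS arrays. Their differences are not exact, and that of KDR lies near background. Cell cycle genes differed by a median of 0.80 (16 of 19 above 0, 0 passing, camera adjusted p = 0.00115, or adjusted p = 0.948 with an estimated correlation, and 2.75e-05 to 0.948 over the alternatives), with 2 higher adjusted over the list alone. The split of 135 and 214 was 143 and 373 with the deposited z scores and 286 and 35 with median scaling, which moved the median of all genes to 0.29. The count was 924 without visceral resveratrol replicate 1 and 111 without replicate 3.

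The effect of HFS against the standard diet differed between the depots in 1 gene of 12917, with 395 at an unadjusted p under 0.05. NEFL was more negative in visceral fat by -1.13 ± 0.21 (adjusted p = 0.0404). Mesothelial markers were more negative at a median of -1.27 (9 of 11 below 0, 0 passing, camera adjusted p = 9.41e-10, or adjusted p = 0.0038 with an estimated correlation, and 1.01e-12 to 0.0203 over the alternatives), with 3 lower adjusted over the list alone. MSLN was at -2.09 ± 0.49, KRT19 at -2.89 ± 0.85 and PKHD1L1 at -1.27 ± 0.40, none past the threshold. MSLN and KRT19 were undetected on all subcutaneous arrays of both groups and PKHD1L1 on all but 1, so these differences largely restate the visceral ones, whose list was lost at the estimated correlation (adjusted p = 0.756). Without visceral standard-diet replicate 1 the median was -0.65, MSLN was at -1.02 and KRT19 at -1.49. Without replicate 2 the median was -1.25, MSLN was at -3.16 (adjusted p = 6.61e-05) and KRT19 at -4.29 (adjusted p = 0.00917). The count of 1 was 11 and 71 without visceral standard-diet replicates 1 and 2, 8 without visceral HFS replicate 2, and 4 without subcutaneous standard-diet replicate 1. It was 0 without visceral HFS replicate 1 or 4, and 0 without subcutaneous HFS replicate 1, 3 or 4.

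Whether resveratrol moved genes against the direction of the diet was measured as a correlation across genes, which are not independent replicates, between the HFS effect and the resveratrol effect. Both use the HFS arrays, so some negative correlation arises with no effect at all. In visceral fat r was -0.521 across 11657 genes (covariance -0.1143), against a mean of -0.283 in 100 simulations with no effect (range -0.922 to 0.645, covariance -0.037), a covariance difference of -0.0773. With the HFS arrays split so that no array served both effects, r averaged -0.315 (covariance -0.0784, range -0.472 to -0.153 over 6 splits). Without standard-diet replicate 1 it was 0.121. In subcutaneous fat r was -0.173 across 12130 genes (covariance -0.0176), against -0.339 with no effect (range -0.838 to 0.534, covariance -0.044), a covariance difference of 0.0264. With the HFS arrays split it was 0.095 (covariance 0.0149, range -0.078 to 0.365 over 20 splits), and without standard-diet replicate 2 it was -0.08. In visceral fat 1 gene was higher and 0 lower on HFS and 0 differed with resveratrol. In subcutaneous fat 0 differed on HFS, so the overlap in the opposite direction was 0 in both depots, and 0 for independent lists.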

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

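The tests of IMP3, the fits within an array set, the animal blocks, the splits by animal and the covariate for probes detected were chosen after the results were seen. In 35 of 355 groups of 4 to 10 arrays examined for the named genes, 1 array lay far from the others by Dixon's test, and chance picks about 1 in 20 groups.

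In visceral fat, HFS replicate 3 lay apart for SNAP25 (6.95, others 4.72 to 4.91), IRS1 (7.07, others 7.5 to 7.54) and CLDN5 (8.53, others 7.21 to 7.42), and HFS replicate 2 for HSPB8 (9.78, others 9.95 to 9.96). Resveratrol replicate 1 lay low for COL6A2 (6.99, others 9.89 to 10.22), ALDH1A2 (9.61, others 11.17 to 11.36) and KDR (4.42, others 4.81 to 4.87), and high for GNLY (7.79, others 6.2 to 6.45). In subcutaneous fat at 24 months, HFS replicate 1 lay apart for AAMDC (11.15, others 11.66 to 11.79) and USF1 (8.97, others 8.09 to 8.32). HFS replicate 4 lay high for ALDH1L1 (9.97, others 8.11 to 8.34), NTS (5.64, others 4.59 to 4.72), ACACB (12.83, others 11.67 to 11.85), KRT19 (4.73, others 4.65 to 4.66) and PKHD1L1 (5.03, others 4.68 to 4.74), and low for RSPRY1 (9.02, others 9.49 to 9.64). Resveratrol replicate 1 lay low for PTGS2 (5.29, others 6.99 to 7.34), LUM (8.27, others 9.79 to 10) and PBDC1 (5.54, others 6.2 to 6.24), and high for KRT19 (4.84, others 4.62 to 4.64) and KDR (5, others 4.72 to 4.75). Resveratrol replicate 2 lay low for USP18 (5.28, others 5.79 to 5.86) and replicate 3 high for DES (5.64, others 4.52 to 4.68). Resveratrol replicate 4 lay apart for TIMP2 (13, others 11.86 to 11.98), IRS2 (7.51, others 8.16 to 8.24), TUBA3E (9.2, others 8.42 to 8.53) and KANK1 (9.87, others 8.59 to 8.69). At baseline, HFS replicate 1 lay high for PLA2G2A (10.02, others 4.79 to 7.2), replicate 4 for GSK3B (10.11, others 9.23 to 9.69), and replicate 8 lay low for AHR (11.62, others 11.91 to 12.16). Standard-diet replicate 4 lay high for IRS1 (9.02, others 7.78 to 7.85). Of the resveratrol baseline arrays, replicate 9 lay high for GSK3B (10.32, others 9.24 to 9.8) and IL6 (5.98, others 5.15 to 5.42), replicate 1 for PBDC1 (5.38, others 4.3 to 4.6), and replicate 7 lay low for CEBPA (10.44, others 11.25 to 12.15).

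Some effects differed between groups by a test of the difference itself. In the unpaired fit the change over time differed between resveratrol and HFS in 102 genes (5 with an animal block and the set as a term), among them DUSP1 (2.15), SH3BGRL (1.83), TUBA3E (1.74), PBDC1 (1.53), LAMP1 (1.47), USE1 (-1.31), RSPRY1 (-1.09), GSK3B (-1.03) and ALKBH8 (-0.97). The effect of HFS differed between depots in 1 gene, NEFL (-1.13). The effect of resveratrol differed between depots in 349 genes, among them COL6A2 (4.4), CLDN5 (2.47), DES (2.01), CEBPA (1.49), PCOLCE2 (-2.57), KANK1 (-2.54), CAT (-2.31), DUSP1 (-2.15) and KDR (-0.95). Probes without a single symbol also changed. Of 5946, 183 passed between resveratrol and HFS in subcutaneous fat at 24 months (174 higher, 9 lower), and 812 over time in the resveratrol group (615 higher, 197 lower).

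More genes were higher than lower with resveratrol against HFS in subcutaneous fat at 24 months, 238 against 33. The number of probes detected stays open. It was 1754 higher on the resveratrol arrays (up to 18673). The slope within the 26 other subcutaneous arrays (up to 17579) gives 0.15 for this gap (standard error 0.07). The 238 genes rose by a mean of 0.85. With the number as a covariate 35 genes passed in place of 271. The 238 averaged 0.68, all above 0. Neither test decides, as the 238 were picked on these arrays and the slope is extrapolated. Of 100 splits of the arrays, 1 gave as many genes (271 real, 75 highest other), so a chance division of the arrays is excluded. Normalization stays open, since with median scaling the median of the 238 genes was 0.53 (0.83 in the reported values), 198 of them lay above 0, and the median standard error was 0.30 in place of 0.17. Relative to all genes the medians were 0.78 and 0.87. An effect of resveratrol, which the design names, may remain beside an effect of RNA or array quality, and these cannot be told apart.

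Subcutaneous genes differed between 24 months and baseline, while array set A held all 24-month arrays and 8 of the baseline ones. The tables argue against the array set as the whole cause. Among 14 baseline arrays of the standard-diet and HFS groups (5 in set A and 9 in set B), the 1379 genes changed over time in the resveratrol group differed between the sets by a signed median of 0.29 (standard error 0.04), against 0.77 over time. Of these genes 1177, or 85.4%, had the sign of the change over time, so the set may give part of it. A change shared by all diets stays open, since the signed median was 0.22 in the standard-diet group (standard error 0.20, n = 2 at 24 months) and 0.24 in the HFS group. Within set A the signed medians were 0.05 in the standard-diet, 0.05 in the HFS and 0.55 in the resveratrol group.

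The splits bear on the changes over time as well. For the resveratrol group 1 of 100 splits gave as many genes (1379 real, 186 highest other), and the highest other kept to an array set. Splits that exchange the arrays of 1 pair were 16, too few for a share under 0.05, with a highest other of 438. For the HFS group 1 of 100 splits gave as many (122 real, 19 highest other), and 1 of 32 splits by pair, with a highest other of 1, so a chance division of the arrays is excluded there. For the difference between resveratrol and HFS over time 1 of 100 splits gave as many (102 real, 15 highest other), and for that between depots 1 of 100 (349 real, 132 highest other). These splits part the arrays of an animal. When all arrays of an animal moved together, 1 of 100 splits gave as many over time (102 real, 3 highest other), and 2 of 100 between depots (349 real, 571 highest other). With an animal block and the set as a term, 3 of 100 gave as many over time (5 real, 41 highest other). A chance division is excluded for the unpaired count over time, not between depots, where another split gave more. Over time the count was 0 in limma with the replicate block and with an animal block within set A (1543 and 1039 at an unadjusted p under 0.05), so that difference stays open once the pairing is used.

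IMP3 was lower in visceral fat of the standard-diet animals. The tables argue against the diet, since the animals with visceral HFS arrays were at 7.74 or above in subcutaneous fat before the diets. A difference between animals that predates the diets may be the source, since the animals with visceral standard-diet arrays were at 4.83 or below at baseline, and 1 other baseline array lay at 4.46. Whether it is a difference in expression or a sequence variant under the single probe was not tested. SNAP25 was high in both animals, at 7.57 to 8.26 at baseline and 7.76 to 8.28 in visceral fat. NEFL (6.08 to 6.31 in visceral fat) was undetected in them at baseline and cannot tell.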

How the results depend on the processing

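The fits within an array set, the animal blocks, the covariate for probes detected and the omission of arrays from the correlations were chosen after the data were seen. Counts are called moved when they differ by more than 1.5 times, and the cause was not tested unless stated. HFS is set against the standard diet where no other group is named.

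With only the arrays of the groups compared, which leaves fewer arrays for the spread, the visceral counts were 2 for HFS (1 reported) and 311 for resveratrol against HFS (0 reported, 247 higher and 64 lower). At 24 months in subcutaneous fat they were 1 for HFS (0), 169 for resveratrol against HFS (271) and 0 for resveratrol against the standard diet (96). They were 0 for HFS at baseline (1), 36 over time on HFS (122), and 0 (1) and 567 (349) for the depot differences of the HFS and resveratrol effects. With all 45 arrays in 1 fit the visceral counts were 23 for HFS, 869 for resveratrol against HFS and 72 for resveratrol against the standard diet (1). The subcutaneous ones were 1 for HFS and 156 for resveratrol against the standard diet. With array weights, resveratrol against HFS gave 3354 in visceral fat, where resveratrol replicate 1 had a weight of 0.402, and 624 in subcutaneous fat, and resveratrol against the standard diet gave 0 in visceral fat. The weights gave 2 for HFS at baseline, 949 over time on HFS, 2751 over time with resveratrol (1379), 267 for the difference over time between resveratrol and HFS (102), and 0 and 2013 for the depot differences.

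With quantile normalization of log2(signal + 16) the counts were 0 for visceral resveratrol against the standard diet, 0 for HFS at baseline, 2 over time on the standard diet (0) and 0 for the depot difference of HFS. With the deposited z scores they were 0 for visceral resveratrol against the standard diet, 792 for subcutaneous resveratrol against HFS, 286 against the standard diet, 0 for HFS at baseline, 81 over time on HFS, 393 for the difference over time and 0 for the depot difference of HFS. In subcutaneous resveratrol against HFS, IL6 turned to 0.11 and IRS1 to 0.19. With median scaling subcutaneous resveratrol gave 6 against HFS and 0 against the standard diet. HFS at baseline gave 0, time on HFS 618, the difference over time 0 and the depot difference of HFS 0. In subcutaneous resveratrol against HFS, PDIA4 turned to -0.07 and TLR2 to -0.15, and the correlation of effects in subcutaneous fat was -0.117 (-0.173). With depots normalized separately visceral resveratrol against the standard diet gave 0. That setting gives no value for comparisons of depots.

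With an adjusted p under 0.1, which by construction adds genes, subcutaneous resveratrol gave 426 against HFS and 169 against the standard diet. Time gave 3 on the standard diet, 332 on HFS and 2105 with resveratrol, the difference over time 162 and the depot difference of resveratrol 712. With the stricter filter, which tests fewer genes, the counts were 157 and 38 for subcutaneous resveratrol, 0 for HFS at baseline, 39 for the difference over time, and 0 and 206 for the depot differences. Without a filter they were 17 over time on the standard diet, 185 on HFS and 0 for the depot difference of HFS. With no variance trend HFS at baseline and the depot difference of HFS gave 0. With every probe, visceral resveratrol against the standard diet gave 0, subcutaneous resveratrol 530 and 241, time on the standard diet 5, the difference over time 234 and the depot difference of resveratrol 662.

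With the array set as a block the counts were 571 and 302 for subcutaneous resveratrol, 149, 543 and 637 over time on the standard diet, on HFS and with resveratrol, 284 for the difference over time and 790 for the depot difference of resveratrol. The block could not be fitted for visceral comparisons. Within array set A they were 1 for subcutaneous HFS at 24 months, 5, 22 and 232 over time, and 0 for the difference over time. Within set B HFS at baseline gave 0. With the replicate block they were 0 for visceral resveratrol against the standard diet, 225 for subcutaneous resveratrol against the standard diet, 0 for HFS at baseline, 1 over time on HFS, 790 over time with resveratrol and 0 for the difference over time. IRS1 turned to 0 for subcutaneous HFS at 24 months. With an animal block and the set as a term time gave 20, 283 and 675, and the difference over time 5. With an animal block within set A these were 76, 45, 537 and 0. With an animal as a random block they were 9 on the standard diet, 354 on HFS and 156 for the difference over time. With probes detected as a covariate the counts were 0 for visceral resveratrol against the standard diet, 35 and 48 for subcutaneous resveratrol, 128 over time with resveratrol, 6 for the difference over time and 640 for the depot difference of resveratrol. With the HFS arrays split between the effects the correlation in subcutaneous fat was 0.095, where the shared arrays no longer give a negative value by construction.

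Leaving out each replicate gave these lowest and highest counts. In visceral fat they were 1 and 8 for HFS, 0 and 1515 for resveratrol against HFS, and 0 and 3 against the standard diet. In subcutaneous fat at 24 months they were 0 and 22, 98 and 287, and 23 and 134, and for HFS at baseline 0 and 3. Over time they were 0 and 47 on the standard diet, 15 and 154 on HFS and 568 and 1107 with resveratrol. For the differences over time they were 0 and 13 (HFS, 0 reported) and 53 and 136 (resveratrol against HFS). Between depots they were 4594 and 5451, with none moved, and for the depot differences 0 and 71 and 111 and 924. The correlations ran from -0.669 to 0.121 in visceral and from -0.247 to -0.08 in subcutaneous fat. Named genes that turned were LEP (-0.58 to 0.01) and IRS1 (-0.48 to 0.11) for visceral HFS, CCL2 for visceral resveratrol against HFS (-0.28 to 1.05), and IL6 for subcutaneous resveratrol against HFS (-0.54 to 0.17). For subcutaneous HFS at 24 months they were HBA1 (-0.09 to 2.08), IRS1 (-0.01 to 0.14), LEP (-0.06 to 0.24) and CCL2 (-1.16 to 2.21). Lists that turned were electron transport for visceral HFS (-0.08 to 0.35), cell cycle over time on the standard diet (-0.15 to 0.52) and, for subcutaneous HFS at 24 months, erythroid (0.12 to 1.39, the test pointing down at 0.12), NRF2 (-0.53 to 0) and immediate early genes (-0.89 to 0). Where 1 array was left in a group, it was assumed to vary like the other groups.

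Of 190 results of named genes, 161 kept direction and call with array weights, 144 with median scaling, 163 with z scores, 174 with quantile normalization and 151 with the replicate block. Of 65 list shifts called, 65 kept direction and call with quantile normalization, 55 with z scores, 9 with fry and 2 with an estimated correlation.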

Other observations

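The fits within an array set and the correlations between changes over time were tests chosen after the results were seen. Other splits of the arrays were counted for the comparisons that gave few genes. In visceral fat between resveratrol and HFS, all 35 splits gave as many genes as the real count of 0 from limma, and the highest other gave 0. Any split meets a count of 0, so this one cannot tell.

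At baseline between HFS and the standard diet, 19 of 100 splits gave as many genes as the real count of 1, and the highest other gave 823. Between resveratrol and HFS, all 100 splits gave as many as the real count of 0 from limma (288 at an unadjusted p under 0.05), and the highest other gave 47. Chance cannot be excluded for the first, and the count of 0 cannot tell for the second, where 90 of the 100 splits gave as many at an unadjusted p under 0.05. The highest other splits followed the array sets, so they point to a structure of the samples. Within array set B both counts were 0 in limma, with 332 and 390 genes at an unadjusted p under 0.05.

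Changes over time correlated across genes, which are not independent replicates, at r = 0.484 between the standard-diet and resveratrol groups, 0.638 between the standard-diet and HFS groups and 0.579 between the HFS and resveratrol groups (12130 genes). Within array set A the values were 0.421, 0.681 and 0.419.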
